A study of Mus musculus with 30 samples.

How the data were processed

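Bulk RNA sequencing of mouse primary microglia was re-analysed, with 30 libraries in 6 groups given by genotype (wild type or Lrrk2 knockout, KO) and treatment (control, LPS or α-synuclein fibrils). Per the labels' protocols, the microglia came from C57BL/6 mice at postnatal day 21, and stranded total RNA libraries depleted of ribosomal RNA were sequenced as single-end reads. Doses, treatment times and sex are not given in the sources used here. The deposited table holds raw expected counts per Ensembl transcript, as whole numbers without normalization. Per the submitters' processing notes, bases were called with CASAVA 1.7.1 and reads were aligned to mm10 with STAR 2.4.2a, and the program that counted reads is not given in the sources used here. Every column of the table belonged to a sample, and no libraries were identical.

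Transcript counts were summed to genes with GENCODE mouse release M21, whose build may differ from that of the authors. Of 94647 transcripts 91320 were matched, and the 3327 unmatched ones, holding 0.779% to 0.891% of the counts of a library, were left out. This gave 38031 genes, of which 25899 had any count. Gene totals ranged from 8936310 to 35677005 with a median of 20432234, and averaged (± SD) 18816867 ± 6286458 in KO control, 21068900 ± 3692584 in KO LPS, 20697051 ± 1442836 in KO fibril, 23037007 ± 8193768 in wild-type control, 21408060 ± 6563061 in wild-type LPS and 24536235 ± 7837933 in wild-type fibril libraries. Counts of near-identical gene copies are uncertain because reads may be shared between them.

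Genes with low counts were removed with the edgeR filter for the 6 groups, which left 14346 genes. Counts were scaled with TMM factors (0.827 to 1.14), and a quasi-likelihood negative binomial model with a mean per group was fitted in edgeR 4.0.16 under R 4.3.3 (24 residual degrees of freedom, common biological coefficient of variation 0.294). CPM values were counts scaled to the library size times the TMM factor, and log2 CPM values used a prior count of 2. The comparisons were KO against wild type in each treatment, LPS and fibrils against control in each genotype, the difference of each response between genotypes, and fibrils against LPS over both genotypes. Genes with an adjusted p (Benjamini-Hochberg) under 0.05 were called. The loss of Lrrk2 was also tested by exact permutation of CPM over all splits into groups of the same sizes, two-sided.

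Gene groups were tested with 32 lists written before the data were examined. They cover cytokines and chemokines, NF-kB feedback, interferon response, antioxidant genes, NADPH oxidase, nuclear and mitochondrial oxidative phosphorylation, glycolysis, lysosome, Rab and trafficking genes, homeostatic and disease-associated microglia, phagocytosis, alternative activation, antigen presentation, cell cycle, cholesterol biosynthesis and efflux, endoplasmic reticulum stress, immediate early genes, ribosomal proteins, markers of 8 other cell kinds, replication histones, genes flanking Lrrk2 and genes known to differ between C57BL/6 substrains. Each list was tested for a shared direction with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated from the data. Where the text says adjusted over the list alone, the p-values of the list's genes were corrected among themselves.

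Genes are named by a rule fixed before the data were examined. It takes (a) the 6 genes most increased and the 6 most decreased among called genes with a mean log2 CPM of at least 2, leaving out genes named only by number, (b) up to 4 called members of each list with the smallest p, or the 2 members with the smallest p where none was called, (c) Lrrk2, Sod2, Tnf, Il1b, Il6, Hmox1, Nqo1 and Nos2, and (d) every gene behind a count of 5 or fewer. Some genes that the rule names are not reported here.

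Alternatives were RLE scaling, library size as the only scaling, another filter and no filter on low counts, limma-voom, DESeq2 1.42.0, models of only the compared groups, each library left out in turn, replicate number as a block, and 1 surrogate variable (sva 3.50.0), with the rotation test fry for lists. Alternatives chosen after seeing the data were a score of other-cell markers as a covariate, leaving out 7 libraries that stand apart (KO control replicates 1, 4 and 6, KO fibril replicate 5, wild-type control replicate 6 and wild-type LPS replicates 1 and 6, listed as extremes of RNA composition, total count or markers, without a set threshold), and protein-coding genes only. Similarity of responses was the Pearson correlation of log2 fold changes across genes, compared with 20 simulations without effects and 20 splits of the controls. The pipeline was tested on simulated data with 14346 genes. For KO against wild type in controls it recovered 64.2% of genes changed 2-fold and 78.8% of genes changed 4-fold, for KO against wild type with fibrils 56.7% and 80.3%, and for LPS against control in wild type 67.2% and 75.8%. In a simulated test of lists the raised list was called and 0 of the 31 others were called. The simulated genes varied independently, while correlations estimated from the data reached 0.929 (interferon response). That test therefore does not measure false calls of lists whose genes vary together.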

Results

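RNA was sequenced from primary microglia, the resident macrophages of the brain, cultured from wild-type C57BL/6 mice and from mice lacking Lrrk2, a large kinase and GTPase linked to Parkinson's disease. The cultures were left untreated as controls, given lipopolysaccharide (LPS, a bacterial cell wall component that activates Toll-like receptor 4), or given fibrils of α-synuclein, the protein that aggregates in Parkinson's disease. The 30 libraries comprised 6 Lrrk2 knockout (KO) controls, 4 KO cultures with LPS, 5 KO cultures with fibrils, 5 wild-type controls, 6 wild-type cultures with LPS and 4 wild-type cultures with fibrils. Counts assigned to genes ranged from 8936310 to 35677005 per library, with a median of 20432234, and 14346 genes were tested. The labels do not say whether replicates of a group came from separate cultures or animals, so all p-values measure the spread between these samples, which may be technical. Values are log2 fold changes ± standard error (SE) from edgeR with adjusted p-values, and CPM values (counts scaled to the library size adjusted with TMM factors) are given as mean ± SD over the libraries of a group.

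Lrrk2, the targeted gene (ENSMUSG00000036273, chromosome 15, 91673175 to 91816120 on mm10), was lower in every KO library than in every wild-type library of the same treatment. Control libraries held 2.78 ± 0.88 CPM in KO (n = 6) against 13.2 ± 2.56 CPM in wild type (n = 5; exact permutation test, two-sided, p = 0.00216). With LPS the values were 3.50 ± 1.00 CPM (n = 4) and 14.9 ± 1.75 CPM (n = 6; exact permutation p = 0.00476), and with fibrils they were 1.30 ± 0.45 CPM (n = 5) and 7.95 ± 1.11 CPM (n = 4; exact permutation p = 0.00794). The fitted KO differences were -2.23 ± 0.21 in controls, -2.09 ± 0.23 with LPS and -2.60 ± 0.24 with fibrils. Fibrils were accompanied by lower Lrrk2 in wild type (-0.73 ± 0.22, adjusted p = 0.0159) and in KO (-1.10 ± 0.22, adjusted p = 6.46e-04). The wild-type call was lost without fibril replicate 3 (adjusted p = 0.0541).

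**Figure D1:**
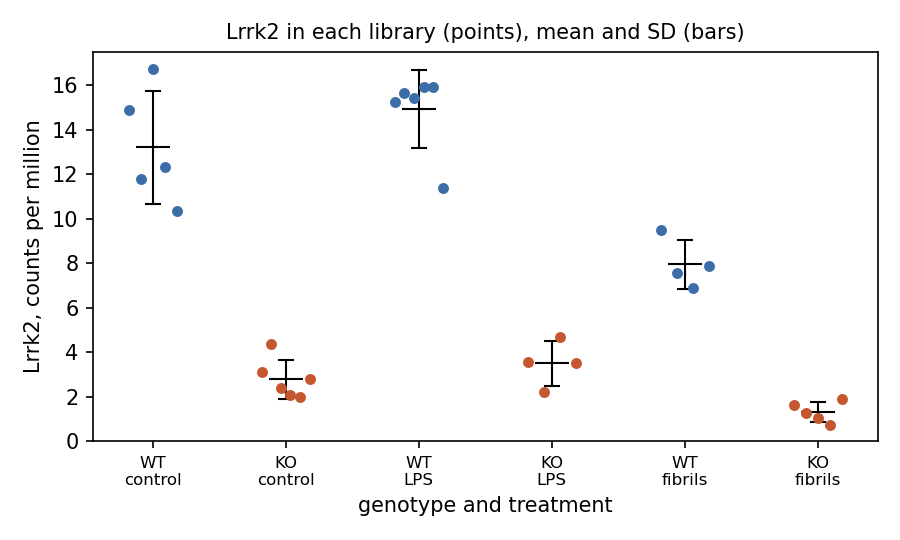
Lrrk2 CPM in each of the 30 libraries by genotype and treatment, with bars for the group mean and SD. All KO libraries lie below all wild-type libraries of the same treatment.

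Untreated KO microglia differed from untreated wild-type microglia in 46 of 14346 genes, of which 22 rose and 24 fell in KO (edgeR quasi-likelihood test, 6 against 5 libraries). The count moved to 17 with only the compared groups, 100 with DESeq2 and 84 with 1 surrogate variable. In alternatives chosen after seeing the data it was 84 with a score of other-cell markers as a covariate and 152, of which 93 rose, without 7 libraries that stand apart. Nnt, the mitochondrial transhydrogenase that supplies NADPH, rose by 0.95 ± 0.09 (adjusted p = 5.96e-07), from 38.5 ± 1.65 CPM in wild type to 74.1 ± 13.3 CPM in KO. Atp10d, a phospholipid flippase, rose by 1.58 ± 0.17, and the endosomal protein gene Wdfy1 rose by 1.16 ± 0.20. Irak4, a kinase of Toll-like receptor signalling (chromosome 15, 94543643 to 94581815), fell by 0.65 ± 0.08 (adjusted p = 8.08e-06), the complement receptor gene C5ar2 fell by 1.90 ± 0.35, and the glutamine transporter gene Slc1a5 fell by 1.08 ± 0.21. Of 13 named genes besides Lrrk2 that were called here, Lilra6 (1.60 ± 0.34) and Pira2 (-1.43 ± 0.24) belong to a receptor family of near-identical copies, so their counts are uncertain.

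Nnt and Wdfy1 made up the 2 of 6 measured genes known to differ between C57BL/6 substrains that rose in untreated KO (2 rose and 1 fell adjusted over the list alone). Among 20 measured genes flanking Lrrk2 on chromosome 15, Irak4 fell and none rose (1 rose and 1 fell adjusted over the list alone). Of 10 cholesterol efflux and liver X receptor (LXR) target genes, 1 fell, Lpcat3, an enzyme that remodels membrane phospholipids (-0.42 ± 0.07, adjusted p = 0.00146), and 3 fell adjusted over the list alone. That list was lower as a whole in KO (camera adjusted p = 9.10e-06; adjusted p = 0.00108 with an estimated correlation). Its estimated correlation was -0.0368, so that test made no allowance for genes that vary together. Between KO and wild type with LPS the list was not called (median -0.03, camera adjusted p = 0.717). The 29 interferon response genes had a median of -0.32 with 0 called by edgeR, also with 0 adjusted over the list alone, and their lower camera call was lost (adjusted p = 0.579 with an estimated correlation). Their mean log2 CPM spread from 2.84 to 7.36 over KO controls and from 5.18 to 6.60 over wild-type controls. In the same comparison the 13 oligodendrocyte lineage markers had a median of 1.90 with 0 called over all genes and 4 higher adjusted over the list alone, and their higher camera call was also lost (adjusted p = 0.579 with an estimated correlation). The 13 astrocyte and 13 fibroblast markers had medians of 0.66 and 0.61 with 0 called by edgeR, also with 0 adjusted over the list alone, and higher camera calls that were lost (adjusted p = 0.607 and 0.579 with an estimated correlation). The antioxidant gene Sod2 (0.09 ± 0.13, adjusted p = 0.95), Tnf (0.20 ± 0.20) and Il1b (-0.06 ± 0.51) were not called. Library size as the only scaling gave 40 called genes, 24 higher and 16 lower. Leaving out wild-type control replicate 5 left 26 called genes, and the calls of Lilra6, Ctla2a (1.23 ± 0.26), Smo (0.69 ± 0.15) and Iqgap2 (-2.11 ± 0.43) each ended without at least 4 single libraries.

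**Figure D2:**
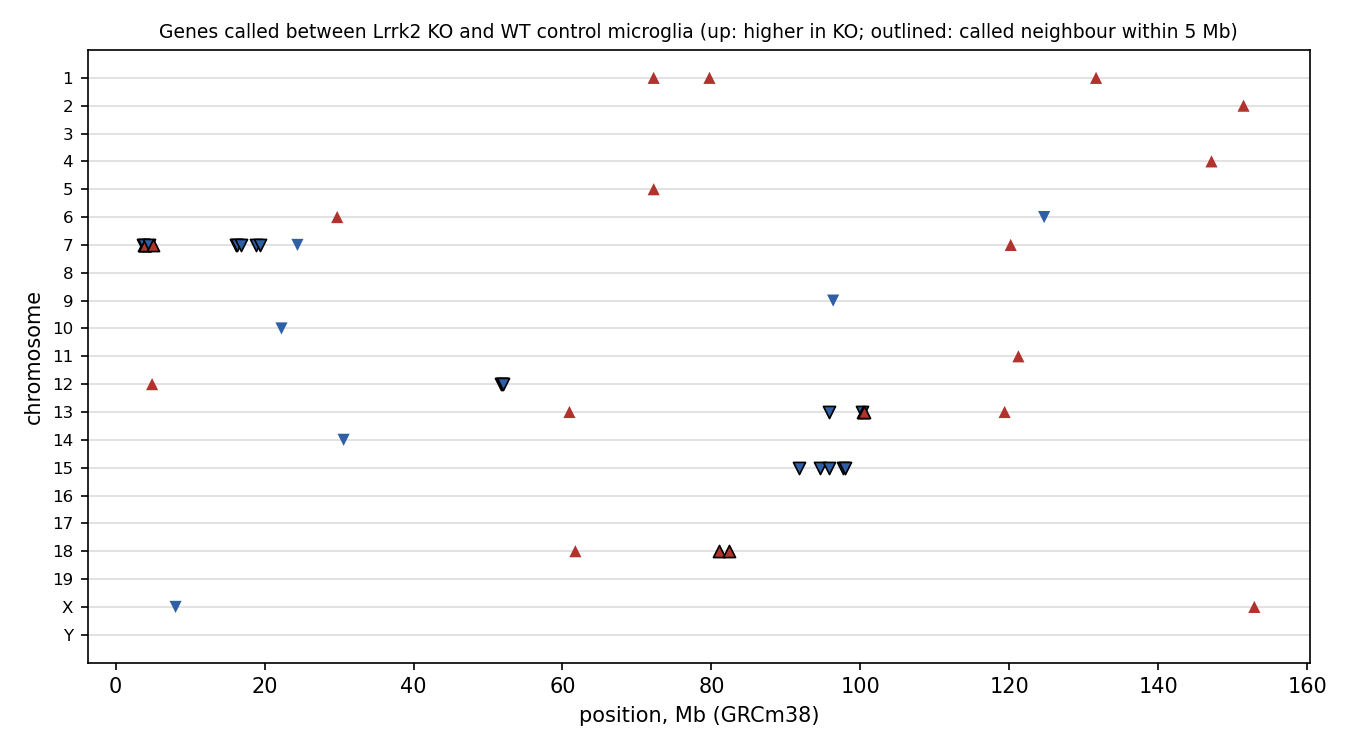
Genome position (Mb, GRCm38) of the 46 genes that differed between untreated KO and wild-type microglia, with upward red marks for higher and downward blue marks for lower expression in KO. Outlined marks, 26 of 46, have another such gene within 5 Mb.

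LPS raised the cytokine and inflammatory genes of wild-type microglia (6 against 5 libraries). Il1a rose by 7.84 ± 0.64 and Cxcl1, a chemokine for neutrophils, by 7.04 ± 0.62. Tnf (ENSMUSG00000024401) rose by 4.32 ± 0.23 (adjusted p = 1.50e-13), from 99.8 ± 25.1 to 1992 ± 379 CPM, with all 6 LPS libraries above all 5 controls. Il1b rose by 5.09 ± 0.62 and Il6 by 4.59 ± 0.75. In all 2171 genes were called, of which 1019 rose and 1152 fell.

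Of 24 measured proinflammatory cytokine and chemokine genes, 19 rose and none fell in wild-type microglia with LPS (20 rose adjusted over the list alone), and of 27 genes of NF-kB feedback and inflammatory effectors, 23 rose (24 adjusted over the list alone). The latter included the feedback inhibitors Tnfaip3 (4.30 ± 0.21) and Nfkbia (2.99 ± 0.20) and the cytokine signalling inhibitor Socs3 (6.12 ± 0.43). Of 19 immediate early genes, 18 rose (19 adjusted over the list alone), including the phosphatase gene Dusp1 (3.64 ± 0.29), Ier3 (3.02 ± 0.20) and Zfp36, which destabilises cytokine mRNAs (2.80 ± 0.19). These 3 lists were higher as wholes with an estimated correlation too (adjusted p = 0.000904, 0.000783 and 2.52e-05 with an estimated correlation, in that order). Of 33 antioxidant and oxidative stress genes, 7 rose (7 adjusted over the list alone), among them Sod2, the mitochondrial superoxide dismutase (ENSMUSG00000006818, chromosome 17, 13006846 to 13040063), by 1.32 ± 0.13, the cystine transporter gene Slc7a11 by 1.35 ± 0.24 and Txnrd1 by 0.90 ± 0.14. The camera call of that list was lost (adjusted p = 0.674 with an estimated correlation), and its median of 0.17 changed sign with library size as the only scaling. Of 33 phagocytosis and scavenger receptor genes, 4 rose and 1 fell (the same counts adjusted over the list alone), with Olr1, a receptor for oxidised lipoprotein, up by 7.40 ± 0.48 and Tlr2 up by 1.83 ± 0.16. The list's median of 0.21 also changed sign with that scaling (adjusted p = 0.674 with an estimated correlation). The 11 alternative activation genes included 3 that rose (3 adjusted over the list alone), such as Il10 (3.81 ± 0.60), and that list's camera call was lost as well (adjusted p = 0.188 with an estimated correlation). Txnip, an inhibitor of thioredoxin, fell by 2.70 ± 0.22, and Zfp763, Zfp870, Zfp157, Zfp61 and Zfp759, which encode zinc finger proteins, each fell by 2.28 to 2.43. Ifnb1, encoding interferon beta, rose by 9.88 ± 0.68. Of 29 interferon response genes it alone was called (1 adjusted over the list alone), and the list had a median of 0.34 (camera adjusted p = 0.0526). With LPS in KO, 1 of these 29 genes rose as well, and the list had a median of -0.54. The list's mean log2 CPM ranged from 2.84 to 7.36 in KO controls and from 5.18 to 6.60 in wild-type controls. With LPS it ranged from 4.88 to 5.74 in KO and from 5.57 to 7.04 in wild type. With such a spread between controls, these medians do not settle whether LPS changed the list.

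Of 14 replication histone genes, whose mRNAs lack poly(A) and which were listed as a check on RNA, 4 fell with LPS in wild type (11 adjusted over the list alone, adjusted p = 0.674 with an estimated correlation). These were Hist2h2ac (-1.46 ± 0.27), Hist1h1e (-1.29 ± 0.27), Hist1h1d (-1.81 ± 0.41) and Hist1h4d (-0.72 ± 0.23). The call of Hist1h4d ended without any 1 of 5 single libraries, with an adjusted p of up to 0.119. Replication histones may also follow cell division. Their mean and the cell cycle mean were both lowest in KO fibril replicate 5 (2.68 and 2.71 log2 CPM). With LPS in wild type 0 of 30 cell cycle genes were called over all genes. Whether RNA quality or division lay behind the histone values was not tested. None of the 13 astrocyte markers (median -0.26), 13 oligodendrocyte lineage markers (-0.24), 7 neuron markers (-0.06), 6 endothelium and pericyte markers (0.18) or 13 fibroblast and leptomeninges markers (-0.15) was called by edgeR in this comparison, over all genes or adjusted over the list alone. With library size as the only scaling the median of all genes moved from -0.02 to -0.23, and 3827 genes were called, 593 higher and 3234 lower.

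KO microglia responded to LPS with 1967 called genes, of which 912 rose and 1055 fell (4 against 6 libraries). With only the compared groups 1110 were called. Tnf rose by 4.11 ± 0.22 (adjusted p = 1.70e-13), from 115 ± 37.7 to 1989 ± 184 CPM, with all 4 LPS libraries above all 6 controls. Il1a rose by 7.32 ± 0.59, Cxcl1 by 7.31 ± 0.60, Il1b by 4.53 ± 0.58 and Il6 by 4.78 ± 0.76. Sod2 rose by 1.18 ± 0.13 and Txnip fell by 2.87 ± 0.26.

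In KO microglia with LPS, 15 of the 24 cytokine and chemokine genes rose (15 adjusted over the list alone), 23 of 27 NF-kB feedback genes rose (23), and 17 of 19 immediate early genes rose (17), and these lists held with an estimated correlation (adjusted p = 0.00338, 0.00196 and 5.51e-05 with an estimated correlation). Of 33 antioxidant genes, 13 rose (15 adjusted over the list alone), including Srxn1, which reactivates peroxiredoxins (1.86 ± 0.27), Slc7a11 (1.90 ± 0.25) and Txnrd1 (1.14 ± 0.14). The KO LPS libraries were split, with a mean log2 CPM of this list of 7.37 and 7.43 in replicates 1 and 2 but 6.86 and 6.89 in replicates 3 and 4 (KO controls 6.52 to 6.79). The mean of astrocyte, oligodendrocyte and fibroblast markers was split likewise, at 0.68 and 0.29 in replicates 1 and 2 but 2.15 and 2.77 in replicates 3 and 4. Hmox1, the heme oxygenase gene, rose by 1.03 ± 0.33, with 2295 and 2678 CPM in replicates 1 and 2 against 815 and 719 in replicates 3 and 4 (KO controls 480 to 1139). Its call ended without any 1 of 6 single libraries, among them KO LPS replicates 1 and 2, with an adjusted p of up to 0.271. The antioxidant list's camera call was lost (adjusted p = 0.258 with an estimated correlation). Of 23 genes of endoplasmic reticulum (ER) stress and the integrated stress response, 8 rose (13 adjusted over the list alone), among them the chaperone gene Hspa5 (0.88 ± 0.15), Atf3 (1.01 ± 0.21) and Ppp1r15a (2.29 ± 0.27), and the camera call was lost (adjusted p = 0.097 with an estimated correlation). Of 46 cytosolic ribosomal protein genes, 1 rose, Rps2 (0.29 ± 0.08; 0 adjusted over the list alone), and the list's median of 0.14 changed sign with library size as the only scaling (adjusted p = 0.895 with an estimated correlation). Among the marker lists of other cells, the fibroblast and leptomeninges list had a median of -1.01 with 1 gene that fell (1 adjusted over the list alone), Dcn (-2.58 ± 0.80). The oligodendrocyte lineage list had a median of -0.72 with 0 called by edgeR and 0 adjusted over the list alone. Of 9 border and peripheral macrophage markers F13a1 rose (2.12 ± 0.63) and Ms4a7 fell (-0.41 ± 0.11; 2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.860). Both calls ended without KO LPS replicate 1 or 2 (adjusted p of up to 0.128 and 0.0645). Library size as the only scaling moved the median of all genes from -0.04 to -0.21 and gave 2835 called genes, 517 higher and 2318 lower. The call of Dcn ended without any 1 of 5 single libraries, with an adjusted p of up to 0.0963, and that of Rps2 without KO LPS replicate 1 or 2, with an adjusted p of up to 0.0606.

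**Figure D3:**
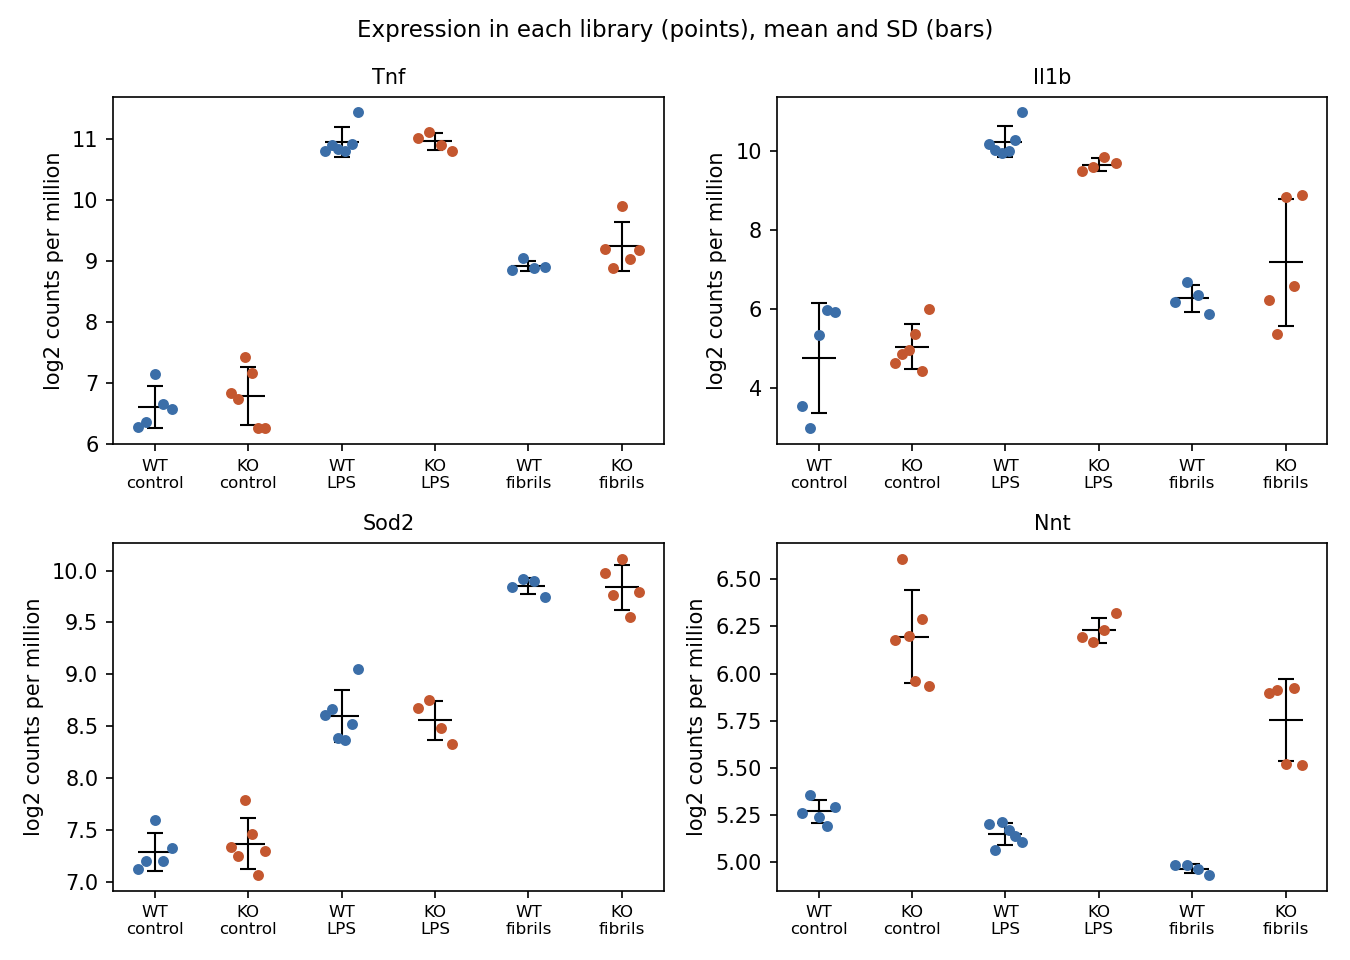
Log2 CPM of Tnf, Il1b, Sod2 and Nnt in each library by genotype and treatment, with bars for the group mean and SD. Tnf and Sod2 lie above all control libraries of the same genotype after both treatments, and Nnt lies higher in KO than in wild type under each treatment.

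No gene differed between the genotypes in its LPS response (0 genes called by edgeR, by DESeq2 and by limma-voom; 600 genes at an unadjusted p under 0.05 in edgeR). The difference, KO minus wild type, was -0.21 ± 0.28 for Tnf, -0.57 ± 0.74 for Il1b, -0.14 ± 0.19 for Sod2 and 0.45 ± 0.10 for Lpcat3, all with adjusted p of 0.99 or more. In simulated data the test of this difference recovered 46.3% of genes changed 2-fold and 56.1% of genes changed 4-fold, so differences of that size could pass unseen.

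Between KO and wild-type microglia that both received LPS, 248 genes were called, 68 higher and 180 lower in KO (4 against 6 libraries). The count was 678 with DESeq2, 1097 with only the compared groups and 1083 without the 7 libraries that stand apart, but 116 without a filter on low counts and 125 with the replicate block. Nnt rose by 1.08 ± 0.10, Atp10d by 1.34 ± 0.17 and Kif21a, a kinesin gene near Lrrk2, by 2.83 ± 0.57, while Irak4 fell by 1.00 ± 0.08 (adjusted p = 3.99e-08). Zfp61 rose by 1.57 ± 0.18 and Ms4a7, a macrophage membrane gene, fell by 0.64 ± 0.11. Among 27 NF-kB feedback genes 2 fell, Tnip1 and Nfkb1 (1 rose and 5 fell adjusted over the list alone), and the list's lower camera call was lost (adjusted p = 0.84 with an estimated correlation). The 29 interferon response genes had a median of -1.32 with 0 called by edgeR, also with 0 adjusted over the list alone. Their lower camera call (adjusted p = 1.06e-06) was lost (adjusted p = 0.84 with an estimated correlation). Their mean log2 CPM was 4.88 to 5.74 in KO and 5.57 to 7.04 in wild type, beside 2.84 to 7.36 in KO controls. Tnf (0.00 ± 0.21), Sod2 (-0.05 ± 0.14) and Il1b (-0.62 ± 0.55) were not called. The 7 neuron markers had a median of 0.73 with 0 called by edgeR and 0 adjusted over the list alone (adjusted p = 0.84 with an estimated correlation). The number of called genes fell to 35, 64 and 125 without KO LPS replicates 4, 1 and 2, to 107, 115 and 123 without wild-type LPS replicates 5, 6 and 3, and rose to 436 and 478 without KO fibril replicate 5 and KO control replicate 6. Tnip1 and Nfkb1 lost their calls without 13 and 15 single libraries, and library size as the only scaling gave 183 called genes, 126 higher and 57 lower, with the median of all genes at 0.11 in place of 0.02.

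Fibrils changed more genes than passed the test with LPS, with 1985 genes that rose and 2231 that fell in wild-type microglia (4216 called, 4 against 5 libraries). The times and doses behind this contrast are not given, so it may not reflect the kind of treatment. With the score of other-cell markers as a covariate, chosen after seeing the data, 2460 genes were called, 1335 higher and 1125 lower. Sod2 rose by 2.55 ± 0.15 (adjusted p = 3.60e-12), from 157 ± 21.2 to 923 ± 48.1 CPM, with all 4 fibril libraries above all 5 controls. Ptges, the prostaglandin E synthase, rose by 3.91 ± 0.39, Acod1, the itaconate-producing enzyme of activated macrophages, by 3.54 ± 0.38, Gpr84 by 3.14 ± 0.37 and Tnf by 2.28 ± 0.22. P2ry12, the purinergic receptor of resting microglia, fell by 1.88 ± 0.40, from 9.86 ± 3.01 to 2.68 ± 0.405 CPM.

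Of 33 antioxidant genes, 17 rose with fibrils in wild type and none fell (17 adjusted over the list alone), among them the glutathione enzymes Gsr (1.47 ± 0.12) and Gss (0.86 ± 0.12), Prdx5 (1.28 ± 0.18) and Nqo1 (1.32 ± 0.34). Of 10 NADPH oxidase genes, 4 rose (5 rose and 1 fell adjusted over the list alone), including the catalytic subunit Cybb (1.41 ± 0.20) and Ncf4 (0.76 ± 0.14), and the list had a positive median (0.36) and test but a negative mean (-0.25). The camera calls of both lists were lost (adjusted p = 0.462 for the antioxidant and 0.266 for the oxidase list with an estimated correlation). Of 27 NF-kB feedback genes 20 rose (22 adjusted over the list alone), with Icam1 up by 1.82 ± 0.22, and of 24 cytokine and chemokine genes 9 rose (9 adjusted over the list alone), with Csf3 up by 6.11 ± 0.73 and Ccl3 up by 2.28 ± 0.34. Those calls were lost too (adjusted p = 0.266 and 0.462 with an estimated correlation). Il1b (1.11 ± 0.56, adjusted p = 0.138) and Il6 (0.38 ± 0.79, adjusted p = 0.750) were not called.

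Of 23 glycolysis and HIF target genes, 16 rose and 2 fell with fibrils in wild type (19 and 2 adjusted over the list alone, adjusted p = 0.504 with an estimated correlation), including the glucose transporter gene Slc2a1 (1.38 ± 0.22), Hk2 (1.03 ± 0.18) and Hif1a (0.52 ± 0.09). Wild-type control replicate 6 had a glycolysis mean of 7.25 log2 CPM (fibril libraries 7.39 to 7.43, other wild-type controls 6.36 to 6.53). Its mean of astrocyte, oligodendrocyte and fibroblast markers (-0.67) was also near the fibril libraries (-0.98 to -0.71). Of 35 lysosome and autophagy genes 5 rose and 1 fell (the same counts adjusted over the list alone; adjusted p = 0.616 with an estimated correlation), and the list's median of 0.17 changed sign with library size as the only scaling. Of 22 Rab and trafficking genes associated with Lrrk2, 8 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.123), with the Lrrk2 substrate genes Rab10 and Rab12 up by 0.69 ± 0.08 and 0.67 ± 0.07. That list had a positive median and test but a mean of -0.14. Nr1h3, encoding LXR alpha, rose by 1.60 ± 0.20. Of 18 homeostatic microglia genes 5 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.254), among them Mef2c (-0.79 ± 0.17) and Gpr34 (-2.40 ± 0.61). Of 22 disease-associated microglia genes 4 rose and 2 fell (5 and 2 adjusted over the list alone, adjusted p = 0.561 with an estimated correlation), with Ch25h up by 1.72 ± 0.35 and Axl down at -1.03 ± 0.29. Wild-type control replicate 6 had a lysosome mean above the fibril libraries (8.59, fibrils 8.40 to 8.45, other controls 7.93 to 8.33). Its disease-associated mean did likewise (9.03, 8.87 to 8.91 and 8.13 to 8.54), but its homeostatic mean did not (5.92, 5.46 to 5.62 and 5.99 to 6.28). Fibril effects on the glycolysis, lysosome and disease-associated lists were thus not separated from RNA of other cells. Of 18 antigen presentation genes 4 fell (2 adjusted over the list alone; camera adjusted p = 0.831), among them Cd86 (-1.74 ± 0.46), and the list's positive median (0.16) differed in sign from its mean and test. Of 30 cell cycle genes, 27 fell (29 adjusted over the list alone; adjusted p = 0.561 with an estimated correlation), including the replication helicase genes Mcm4 (-1.24 ± 0.23) and Mcm6 (-1.09 ± 0.21) and E2f1 (-0.70 ± 0.11). Of 14 replication histone genes, whose mRNAs lack poly(A), 9 fell (9 adjusted over the list alone; adjusted p = 0.561 with an estimated correlation). Of 13 mitochondrially encoded genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.27), and of 60 nuclear-encoded oxidative phosphorylation genes 1 rose, Cycs (0.69 ± 0.14), and 1 fell, Sdha (-0.39 ± 0.15; 1 rose adjusted over the list alone; camera adjusted p = 0.071).

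Markers of other cells were lower in the same comparison. Of 13 astrocyte markers 10 fell (10 adjusted over the list alone), such as Gfap (-4.68 ± 1.21), of 13 fibroblast and leptomeninges markers 8 fell (11), such as Col1a1 (-7.81 ± 1.61) and Col3a1 (-6.20 ± 1.21), and of 7 neuron markers 3 fell (5), such as Map2 (-3.36 ± 0.84). These 3 camera calls were lost (adjusted p = 0.561 for each with an estimated correlation). Of 13 oligodendrocyte lineage markers 3 fell (3), of 6 endothelium and pericyte markers 4 fell and 1 rose (4 and 1), and of 2 lymphocyte markers 1 fell (1), with camera adjusted p of 0.119, 0.297 and 0.291. Border and peripheral macrophage markers showed 2 higher and 1 lower of 9 (3 and 1; camera adjusted p = 0.747), and neutrophil and mast cell markers 2 higher of 3 (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.245). The mean log2 CPM of astrocyte, oligodendrocyte and fibroblast markers was -0.83 ± 0.12 (SD, n = 4) in wild-type fibril libraries against 1.19 ± 1.23 (n = 5) in wild-type controls. Slopes on that mean within 21 control and LPS libraries gave the observed sign for 3166 of the 4216 called genes, and at least 50% of the size too for 890 (r = 0.658 over all genes). Calls of Col1a1, Col3a1, Gfap and Map2 ended with limma-voom, and the call of Sdha (-0.39 ± 0.15) ended without any 1 of 6 single libraries, with an adjusted p of up to 0.131. Library size as the only scaling moved the median of all genes from -0.05 to -0.25 and gave 4562 called genes, 793 higher and 3769 lower.

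**Figure D4:**
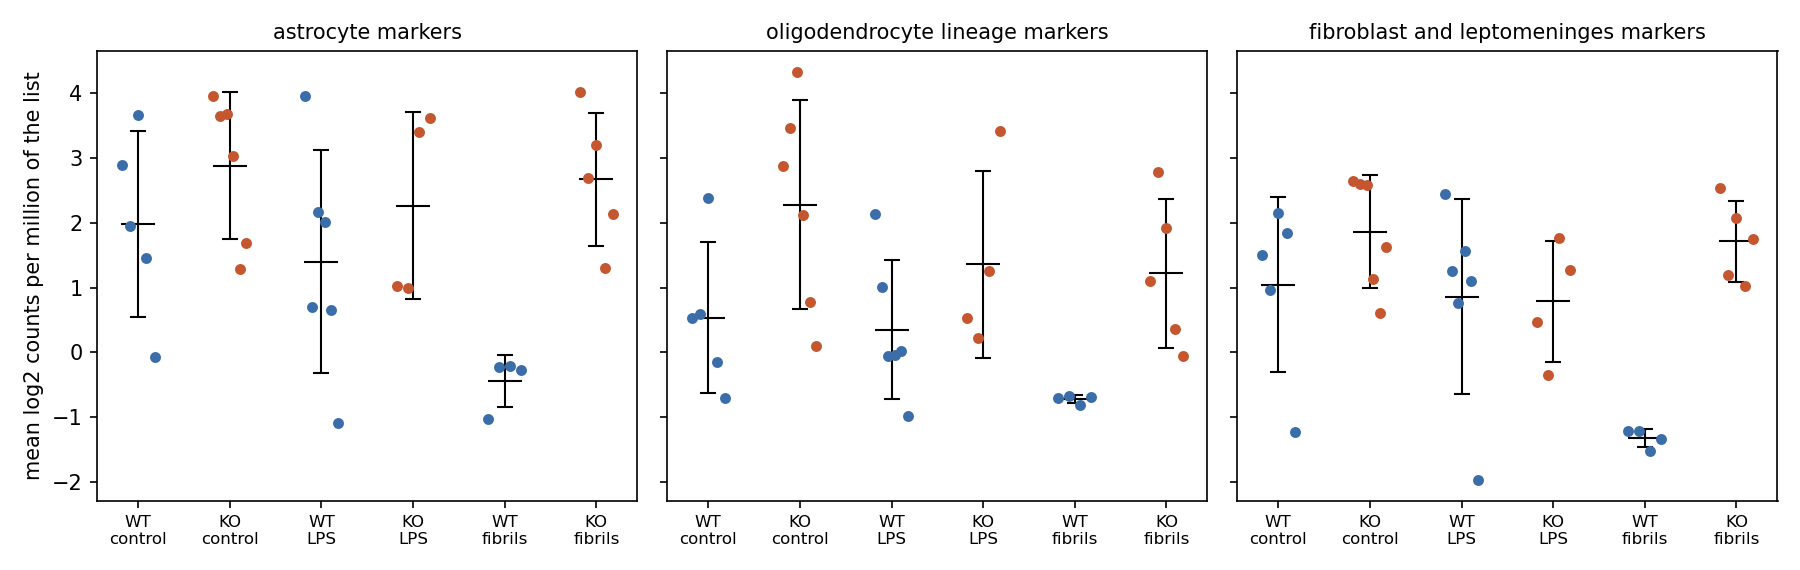
Mean log2 CPM of astrocyte, oligodendrocyte lineage and fibroblast marker genes in each library, with a panel for each list and bars for the group mean and SD. In the mean over these lists, which is not drawn, the 4 wild-type fibril libraries lie close together (-0.98 to -0.71). In that mean wild-type LPS replicate 6 lies below them (-1.34), wild-type control replicate 6 just above (-0.67) and all other libraries at 0.29 or higher. Single panels differ from it, such as -0.35 for fibroblast markers in KO LPS replicate 2.

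In KO microglia, fibrils called 3402 genes, of which 1746 rose and 1656 fell (5 against 6 libraries). With only the compared groups 1541 were called, 836 higher and 705 lower. Sod2 rose by 2.47 ± 0.13 (adjusted p = 6.79e-13), from 167 ± 30 to 925 ± 139 CPM, with all 5 fibril libraries above all 6 controls. Adm, the vasodilator adrenomedullin, rose by 4.63 ± 0.44, Acod1 by 3.89 ± 0.35, Ptges by 3.83 ± 0.35, Tnf by 2.44 ± 0.20, Il1b by 2.70 ± 0.53 and Il6 by 3.13 ± 0.73. Gpr34 fell by 3.71 ± 0.57, the organic anion transporter gene Slco2b1 by 4.46 ± 0.46 and P2ry12 by 2.27 ± 0.37. The KO fibril libraries were split for Il1b, at 457 and 478 CPM in replicates 3 and 5 but 41.1 to 96.3 in the other 3 (KO controls 21.7 to 64.3), and for Il6, at 11.9 and 14.5 CPM against 0.879 to 3.76 (KO controls 0.0994 to 1.83). Both calls held without either replicate (adjusted p of up to 0.00271 and 0.0115), and leaving out both together was not tried. The call of Il6 was lost with limma-voom.

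Of 27 NF-kB feedback genes, 24 rose in KO with fibrils (24 adjusted over the list alone), among them Icam1 (2.03 ± 0.20) and Socs3 (3.70 ± 0.37), and the list held (adjusted p = 0.0328 with an estimated correlation). Of 24 cytokine and chemokine genes 14 rose (15 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with Csf3 up by 7.48 ± 0.69. Of 33 antioxidant genes 9 rose and 1 fell (the same adjusted over the list alone; adjusted p = 0.796 with an estimated correlation), including Gsr (1.17 ± 0.11), Slc7a11 (1.42 ± 0.24) and Prdx5 (0.98 ± 0.17), while Nqo1 was not called (0.65 ± 0.31, adjusted p = 0.128). The mean log2 CPM of the antioxidant list was 6.73 and 6.71 in KO fibril replicates 3 and 5, within the KO controls (6.52 to 6.79), and 6.95 to 7.23 in the others. Of 10 NADPH oxidase genes 4 rose (4 adjusted over the list alone; camera adjusted p = 0.0649), including Cybb (1.05 ± 0.18) and Ncf4 (0.73 ± 0.12). Of 18 homeostatic microglia genes 6 fell (6 adjusted over the list alone; adjusted p = 0.21 with an estimated correlation), with Mef2c at -1.30 ± 0.15 and P2ry13 at -1.31 ± 0.25. Of 30 cell cycle genes 16 fell (29 adjusted over the list alone; adjusted p = 0.796 with an estimated correlation), and of 21 cholesterol biosynthesis genes 3 rose (7 adjusted over the list alone; adjusted p = 0.863 with an estimated correlation). Of 22 Rab and trafficking genes 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.394), with Rab10 up by 0.66 ± 0.07. The astrocyte and fibroblast marker lists had medians of -0.02 and -0.26 with 0 called by edgeR, over all genes or adjusted over the list alone. Other markers were called, with Pecam1 of endothelium at -2.07 ± 0.48 (1 of 6 fell, 1 adjusted over the list alone), and Cspg4 of the oligodendrocyte lineage at -1.20 ± 0.39 (1 of 13 fell, 0 adjusted over the list alone). Of 9 border macrophage markers Ms4a6c rose (1.20 ± 0.33) and Mrc1 fell (-0.93 ± 0.14), the same adjusted over the list alone. Of 14 replication histone genes 6 fell (8 adjusted over the list alone; adjusted p = 0.796 with an estimated correlation), such as Hist1h1c (-1.30 ± 0.22). The call of Cspg4 ended without KO control replicate 5, KO fibril replicate 3 or KO fibril replicate 5 (adjusted p of up to 0.155). Library size as the only scaling moved the median of all genes from -0.04 to -0.13 and gave 3234 called genes, 1002 higher and 2232 lower.

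**Figure D5:**
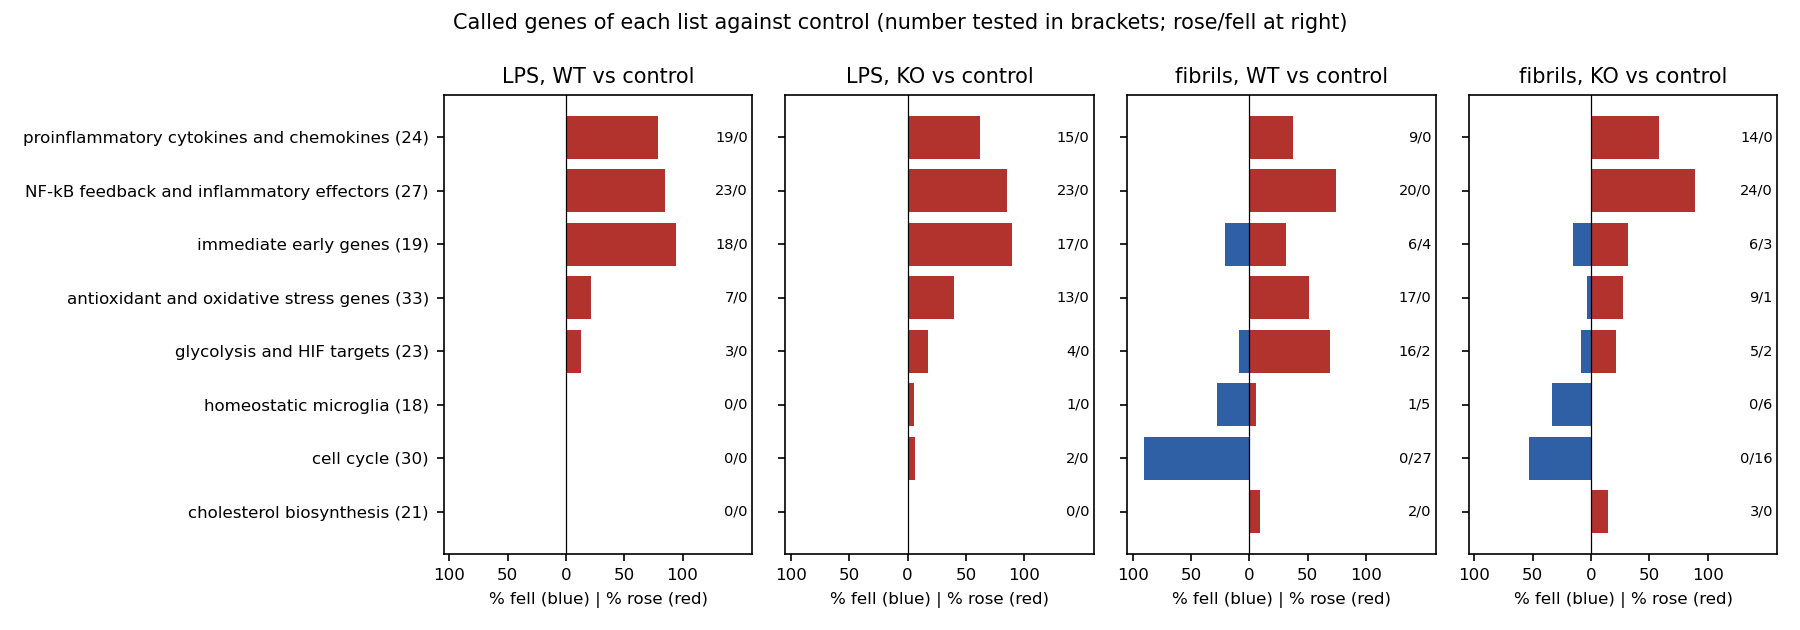
Percent of the tested genes of 8 lists that rose (red) or fell (blue) against control, for LPS and fibrils in wild type and KO, with the numbers that rose and fell at the right. Cytokine, NF-kB feedback and immediate early genes rose with LPS in both genotypes, while of 30 cell cycle genes 27 fell with fibrils in wild type and 16 in KO, list calls that were lost (adjusted p = 0.561 and 0.796 with an estimated correlation).

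No gene passed the test for a difference between the genotypes in its fibril response (0 called by edgeR and by limma-voom, 71 by DESeq2; 1667 at an unadjusted p under 0.05 in edgeR). The difference, KO minus wild type, was -0.08 ± 0.19 for Sod2, 0.16 ± 0.29 for Tnf, 1.59 ± 0.76 for Il1b (adjusted p = 0.419), 2.75 ± 1.08 for Il6 (adjusted p = 0.349), -0.67 ± 0.46 for Nqo1 and -0.47 ± 0.10 for Rab12 (adjusted p = 0.20). The differences for Il1b and Il6 were 1.18 and 2.42 without KO fibril replicate 3, and 1.13 and 2.23 without KO fibril replicate 5. The other 3 KO fibril libraries held 41.1 to 96.3 CPM of Il1b, and wild-type fibril libraries 58.4 to 103. The count was 39 with the replicate block nested within genotype, 9 with 1 surrogate variable, 12 without wild-type control replicate 6 and 250 without the 7 libraries that stand apart. In simulated data this test recovered 49.3% of genes changed 2-fold and 65.2% of genes changed 4-fold.

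Between KO and wild-type microglia that both received fibrils, 1282 genes were called, 756 higher and 526 lower in KO (5 against 4 libraries). The count was 1978 with DESeq2, 2114 with the replicate block and 2580 without the 7 libraries that stand apart, but 575 with limma-voom, 826 without a filter, 757 with only the compared groups and 699 with 1 surrogate variable. Nnt (0.80 ± 0.10), Irak4 (-0.65 ± 0.08), C5ar2 (-2.96 ± 0.41) and Lrrk2 itself were among the genes called under each alternative tried. Nnt is known to differ between C57BL/6 substrains, Irak4 flanks Lrrk2, and C5ar2 lay in a group of neighbouring called genes on chromosome 7 in controls. Of 68 named calls 29 held with every single library left out. Sod2 (0.00 ± 0.14) and Tnf (0.36 ± 0.22) were not called, with Sod2 at 925 ± 139 CPM in KO and 923 ± 48.1 CPM in wild type. Of 23 glycolysis and HIF target genes 13 fell (16 adjusted over the list alone), such as Pgk1 (-0.74 ± 0.20). Of 35 lysosome and autophagy genes 7 fell (11), such as the cathepsin gene Ctss (-0.74 ± 0.16), and of 33 antioxidant genes 6 fell and 1 rose (9 and 1), such as Gss (-0.57 ± 0.12). All 3 camera calls were lost (adjusted p = 0.375 for each with an estimated correlation). Of 10 LXR target genes 3 fell (6 fell and 1 rose adjusted over the list alone), among them Lpcat3 (-0.39 ± 0.08) and Apoe (-0.94 ± 0.21). That list held (adjusted p = 0.0262 with an estimated correlation, which was below 0 for this list). Rab12 fell by 0.32 ± 0.07 and the receptor gene Csf1r, on which microglia depend, by 0.90 ± 0.16.

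Alongside these genes, 9 of 13 astrocyte markers (11 adjusted over the list alone), 8 of 13 fibroblast markers (10) and 4 of 7 neuron markers (5) rose in KO, such as Gfap (5.26 ± 1.23), Col1a2 (6.78 ± 1.39) and Tubb3 (3.42 ± 0.81), with camera calls that were lost (adjusted p = 0.375, 0.332 and 0.375 with an estimated correlation). The mean of astrocyte, oligodendrocyte and fibroblast markers was 1.87 ± 0.74 (SD, n = 5) in KO fibril libraries against -0.83 ± 0.12 (n = 4) in wild type. With that mean as a covariate 69 genes were called, and the calls of Gfap, Col1a2, Tubb3, Pgk1, Ctss, Gss, Apoe, Rab12 and Csf1r ended. The camera direction of the lysosome and autophagy list also reversed with it (median 0.057, camera adjusted p = 0.932). The 1282 calls became 375, 419, 475 and 479 without wild-type fibril replicates 1, 2, 3 and 4, and 742 and 651 without KO fibril replicates 1 and 3, and the calls of Gfap and Tubb3 ended without wild-type fibril replicate 1 (adjusted p = 0.0508 and 0.0545). The call of Pgk1 ended without any 1 of 6 single libraries, with an adjusted p of up to 0.0653. Library size as the only scaling gave 1217 called genes, 1027 higher and 190 lower, with the median of all genes at 0.16 in place of 0.01.

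Fibrils and LPS were compared over both genotypes, with 6069 genes called, 3097 higher and 2972 lower with fibrils (9 against 10 libraries). Treatment times and doses are not given for either, so the kind of treatment cannot be told apart from time or dose here. Sod2 was higher with fibrils by 1.26 ± 0.10 (adjusted p = 1.10e-10), Nqo1 by 1.08 ± 0.24, Nr1h3 by 1.20 ± 0.14 and Txnip by 3.05 ± 0.18. Tnf was lower with fibrils (-1.86 ± 0.16), as were Il1a (-4.82 ± 0.41), Ifnb1 (-7.41 ± 0.43) and the nuclear receptor gene Nr4a1 (-7.31 ± 0.61). All 19 immediate early genes fell (19 adjusted over the list alone), and that list held (adjusted p = 0.00117 with an estimated correlation). Of 30 cell cycle genes 30 fell (30 adjusted over the list alone), of 24 cytokine genes 14 fell (14), of 11 alternative activation genes 8 fell and 1 rose (9 and 1), and of 21 cholesterol biosynthesis genes 15 rose (17), among them Mvd (1.37 ± 0.29) and Lss (1.21 ± 0.31). The camera calls of those 4 lists were lost (adjusted p = 0.455, 0.321, 0.0934 and 0.813 with an estimated correlation). Some markers of other cells fell with fibrils in the same comparison, although none of their lists was called, with 3 of 13 astrocyte markers that fell (0 adjusted over the list alone), such as Gfap (-1.94 ± 0.73), and 4 of 13 of the oligodendrocyte lineage (4), such as Pdgfra (-2.27 ± 0.66). The same held for 3 of 7 markers of neurons (3 adjusted over the list alone), such as Map2 (-1.99 ± 0.53), and 6 of 13 of fibroblasts (6 adjusted over the list alone), such as Col1a1 (-2.84 ± 0.97). Of 14 replication histone genes 4 fell (2 adjusted over the list alone), such as Hist1h1a (-1.36 ± 0.30) and Hist1h1c (-0.78 ± 0.17). The camera adjusted p of these 5 lists was 0.292, 0.341, 0.169, 0.358 and 0.134. The mean of astrocyte, oligodendrocyte and fibroblast markers was lower with fibrils in wild type only (-0.83 ± 0.12 against 0.87 ± 1.34 with LPS), and in KO it was 1.87 ± 0.74 with fibrils and 1.47 ± 1.18 with LPS. The call of Gfap ended without any 1 of 8 single libraries (adjusted p of up to 0.118) and that of Col1a1 without KO LPS replicate 3 or wild-type fibril replicate 2 (up to 0.117).

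Across genes, the fold changes of LPS and of fibrils correlated with r = 0.348 in wild type and r = 0.334 in KO over 14346 genes, which are not independent replicates. The wild-type value was 0.221 without wild-type LPS replicate 6 and 0.489 without wild-type control replicate 6 (jackknife SE 0.227). Both responses share their control libraries, and unchanged groups simulated against the same controls gave r = 0.485 and 0.432. The covariance was 0.160 against a simulated 0.0645 in wild type and 0.113 against 0.0565 in KO. With the controls split between the comparisons, r averaged 0.197 over 20 splits in wild type, from -0.109 to 0.451, and 0.112 in KO, from -0.015 to 0.295. In wild type 435 genes rose with both treatments and 213 fell with both, while 38 rose with LPS and fell with fibrils and 57 did the opposite. In KO these counts were 419, 219, 27 and 45, and no overlap expected from shared controls was computed. Between genotypes, which share no libraries, the fold changes correlated with r = 0.732 for LPS and r = 0.554 for fibrils. LPS raised 644 genes and lowered 730 in both genotypes (independent lists 64.8 and 84.7), and fibrils raised 1213 and lowered 924 in both (independent lists 242 and 258).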

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

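The tests of neighbouring genes, of the marker score as a covariate, of response differences among the fibril genes and of closeness between libraries were chosen only after the result was seen, while the test by slopes and all splits of the samples were planned.

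Of 120 group measures, 10 held a sample far from the others of its group, where chance gives about 1 in 20 groups. KO control replicate 1 held 10.8% small and ribosomal RNA (others 5.14% to 5.90%). Il6 was 32.6 CPM in KO LPS replicate 3 (others 15.8 to 17.4), and Tnf was 955 CPM in KO fibril replicate 3 (others 469 to 586). In wild-type LPS replicate 6 Lrrk2 was 11.4 CPM (others 15.3 to 15.9), Tnf 2757 (others 1776 to 1921) and Il1b 2029 (others 998 to 1249). Mean log2 CPM of markers stood apart for endothelium and pericytes in wild-type LPS replicate 1 (0.974, others 0.336 to 0.512), and in wild-type fibril libraries for astrocytes in replicate 1 (-1.03, others -0.272 to -0.208), neurons in replicate 2 (-2.02, others -2.47 to -2.41) and border macrophages in replicate 4 (5.43, others 5.50 to 5.51).

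The LPS response of 10 lists differed between genotypes by camera at the preset correlation. KO was lower for cytokines (adjusted p = 0.0314, median difference -0.54) and fibroblast markers (0.0375, -0.75), and higher for antioxidant genes (0.00483, 0.23), nuclear oxidative phosphorylation (3.27e-04, 0.10), glycolysis (0.0314, 0.29), cell cycle (2.98e-04, 0.32), LXR targets (0.00519, 0.39), ER stress (0.0314, 0.22), ribosomal proteins (3.01e-05, 0.13) and replication histones (3.32e-05, 0.71). None was called with an estimated correlation (adjusted p from 0.0677 to 0.77).

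The fibril response of 11 lists differed between genotypes by the same test. KO was higher for NF-kB feedback genes (adjusted p = 0.00226, median difference 0.37) and for markers of astrocytes (1.94e-05, 3.47), neurons (0.0232, 2.57) and fibroblasts (1.02e-04, 3.06). KO was lower for antioxidant genes (9.27e-04, -0.29), nuclear oxidative phosphorylation (0.0347, -0.08, positive with library size as the only scaling), glycolysis (3.27e-08, -0.56), lysosome (7.57e-08, -0.28), homeostatic microglia (0.00473, -0.41), disease-associated microglia (1.02e-04, -0.49) and phagocytosis genes (0.00293, -0.15). None was called with an estimated correlation (adjusted p from 0.585 to 0.941).

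Genes called between untreated KO and wild-type microglia lay close together on the genome. Of 46 genes, 26 had another called gene within 5 Mb (random sets 9.84 on average, 26 at most), and without chromosome 15 it was 21 of 41 (random sets 8.14 on average, 22 at most), in groups such as Pirb, Pira2 and Lilra6 on chromosome 7 and Iqgap2, Naip2 and Naip3 on chromosome 13. Pirb, Pira2 and Lilra6, like Naip2 and Naip3, are neighbouring members of gene families whose reads may be shared, so their calls may not be independent. The random sets, drawn gene by gene, made no allowance for that, so part of the excess may come from it. Segments of another strain carried with the KO line are a candidate explanation. All 26 kept their direction with LPS and with fibrils, but so did 16 of the 20 genes without a called neighbour, and the 46 genes with the smallest p had such a neighbour in 23 cases for LPS in wild type, 14 for LPS in KO, 6 for fibrils in wild type and 8 for fibrils in KO. Loss of Lrrk2 acting on these genes one by one stays open, and so does it for the 20 genes without a called neighbour, which 1 KO line cannot separate from strain variants. Of 100 splits of the control samples 5, the real one included, gave at least the real 46 called genes (highest other 150), so chance cannot be excluded for the count. Splits that call more genes than the real one point to a structure of the samples.

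RNA of other cell types may account for many of the 1282 genes called between KO and wild type with fibrils. Slopes on the marker score within 21 control and LPS libraries gave the observed sign and at least 50% of the size for 825 of them, or 64.4%. With the score in the model 69 genes were called, 48 of them among the 1282, and the median size fell from 1.74 to 0.547 while the median SE went from 0.475 to 0.430. The score also takes up any real genotype effect that runs along with it. It did not overlap between the groups (-0.98 to -0.71 in wild type, 0.89 to 2.55 in KO), so this model extrapolates. A fibril response that depends on Lrrk2 stays open, with 0 of these genes past the test of the difference itself in edgeR (1667 of all genes at an unadjusted p under 0.05, 71 past the test by DESeq2, 0 by limma-voom).

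The 4 wild-type fibril libraries lay close together. The median chi-square between pairs ran from 1.09 to 1.64, where sampling noise alone gives 0.455. This argues against a single library sequenced 4 times. It does not exclude it, since expected counts and differences between sequencing runs may also raise the value, and no repeated library was available for comparison. Separate libraries of 1 culture may give such values, at 1.64 for the pair furthest apart, and stay open. Single pairs in other groups were as close, with KO LPS replicates 1 and 2 at 1.36 and wild-type LPS replicates 3 and 4 at 1.38, and wild-type LPS replicates 4 and 5 lay just beyond at 1.72, while the median over all pairs was 5.53 and 4.17 in those groups and 1.55 in wild-type fibril libraries. No biological explanation was tested. If close libraries of any group share a culture, the p-values of comparisons with them are too small.

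In 100 splits each, the real groups called the most genes for LPS against control in wild type (2171, highest other split 1871) and KO (1967, highest other 476). The same held for fibrils against control in wild type (4216, highest other 3952) and KO (3402, highest other 2844). It also held for KO against wild type with LPS (248, highest other 29) and with fibrils (1282, highest other 834), and for fibrils against LPS (6069, highest other 3844). In each of these only 1 split, the real one, gave as many. The splits treat libraries as independent, so they cannot exclude chance where libraries of a group share a culture. For the response differences, with 0 genes called by edgeR, all 100 splits gave as many, which was certain in advance and says nothing on chance. The real groups gave 600 (LPS) and 1667 (fibrils) genes at an unadjusted p under 0.05, with 0 and 71 called by DESeq2 and 0 and 0 by limma-voom. The highest other split called 564 genes for LPS and 1369 for fibrils. Splits calling that many genes point to a structure of the samples.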

How the results depend on the processing

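The marker score as a covariate, leaving out 7 libraries and protein-coding genes only were tests chosen after seeing the data, and all others were planned. Of 532 called values of named genes 310 were called under every alternative run, 222 were lost under at least 1 and 1 reversed, and of 104 list calls 10 were called under every alternative. Most gene calls were lost with the covariate (117), limma-voom (87), only the compared groups (67) and library size only (64), and 133 were lost without at least 1 single library. The cause was not tested except where fewer samples or the covariate's own construction show it.

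Called genes for KO against wild type in controls (46) were 100 with DESeq2, 17 with only the compared groups, 84 with 1 surrogate variable, 84 with the covariate, 152 without the 7 libraries, and 26 (without wild-type control replicate 5) to 58 with single libraries left out. With LPS (248) they were 678 with DESeq2, 116 without a filter, 1097 with only the compared groups, 125 with the replicate block, 1083 without the 7 libraries, and 35 (without KO LPS replicate 4) to 478 (without KO control replicate 6) with single libraries left out. With fibrils (1282) they were 1978 with DESeq2, 575 with limma-voom, 826 without a filter, 757 with only the compared groups, 2114 with the replicate block, 699 with 1 surrogate variable, 69 with the covariate, 2580 without the 7 libraries, and 375 (without wild-type fibril replicate 1) to 1639 with single libraries left out. LPS against control gave 3827 in wild type with library size only and 1110 in KO with only the compared groups. Fibrils against control gave 2460 in wild type with the covariate and 1541 in KO with only the compared groups. The fibril response difference (0 in edgeR, 1667 at an unadjusted p under 0.05, 0 by limma-voom) was 71 with DESeq2, 39 with the nested replicate block, 9 with 1 surrogate variable, 250 without the 7 libraries, and 0 to 12 (without wild-type control replicate 6) with single libraries left out.

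With an estimated correlation, called lists went from 8 to 1 for KO in controls, 10 to 3 and 11 to 3 for LPS in wild type and KO, 13 to 0 and 7 to 1 for fibrils in wild type and KO, 10 to 0 and 11 to 0 for the LPS and fibril response differences, 10 to 0 and 15 to 1 for KO with LPS and with fibrils, and 9 to 1 for fibrils against LPS. With fry they were 1 for KO in controls, 1 and 0 for the response differences and 3 for KO with LPS, and with the covariate 8 for KO with fibrils. Single libraries left out gave 8 to 15 (without wild-type control replicate 1; 13 without replicate 2) for KO in controls and 6 to 11 (without KO control replicate 5) for fibrils in KO.

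With the covariate Scd1 with fibrils in wild type reversed (0.16). The camera direction of some lists reversed too, given here with their medians under the covariate. These were lists for KO in controls (astrocyte -0.55, fibroblast -0.20), fibrils in wild type (lysosome -0.054) and KO with fibrils (interferon 0.89, lysosome 0.057, disease-associated microglia 0.031, phagocytosis 0.13, ribosomal 0.018, oligodendrocyte 0.27). The direction is that of the test, and the median need not share its sign. Lrrk2 in controls stayed between -2.42 and -2.14 without single libraries. By their labels the samples share only a number. In 0 of 15 group pairs was every same-number correlation over 0.1, and 12 of 30 libraries correlated best with their own number. For wild-type control and LPS libraries the same-number correlation averaged 0.289, against -0.0537 for other numbers (4 of 5 over 0.1). For KO and wild-type controls it averaged 0.220 against -0.0433 (4 of 5), but for KO LPS and KO fibril libraries -0.176 against 0.0435 (1 of 4). A link by number, which the main model leaves out, was thus not excluded. No chance level was computed for these values, and links across numbers were not tested. KO control replicate 6 and KO fibril replicate 5, for example, held 1.02% and 1.09% mitochondrial mRNA (all other libraries 1.57% to 2.61%). Titles and descriptions disagree on the numbers of wild-type control replicates 5 and 6, and the titles were used, so this check and the block may rest on wrong numbers for these (2114 genes for KO with fibrils). Leaving out 7 libraries picked as extremes also narrows the spread within groups, so the higher counts without them (250 for the fibril response difference) are no support for the genes called there. The replicate block ended 19 gene calls and 9 list calls. The tests of response differences, at the depth and number of libraries here, recovered 14.9% (LPS) and 11.9% (fibrils) of genes changed 1.5-fold in simulated data.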

Other observations

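The tests of zinc finger genes with LPS and of cholesterol genes with the marker covariate were chosen only after the result was seen, while those of zinc finger genes with fibrils were planned.

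Genes of zinc finger proteins (320 genes named Zfp), many of them repressors of transcription, fell as a group with LPS. In wild type 190 fell and 12 rose, where random lists of the same expression gave 32.2 on average and 56 at most, and in KO 189 fell and 12 rose, where random lists gave 29.3 on average and 51 at most. Their medians were -0.66 and -0.68 (-0.87 and -0.85 with library size as the only scaling, where the median of all genes was -0.23 and -0.21). Zfp61 (-2.29 ± 0.17) and Zfp157 (-2.30 ± 0.18) were among those that fell in wild type. With fibrils 43 fell in wild type and 44 in KO, with medians of -0.15 and -0.16 (all genes -0.05 and -0.04), and the counts were not above random lists (64.6 on average and 92 at most in wild type, 73 at most in KO). With an estimated correlation the unadjusted camera p for fibrils was 0.111 in wild type and 0.0424 in KO, both lower. Lower zinc finger expression may thus belong to the LPS response, where 190 and 189 genes fell, which is a hypothesis found and tested on the same data, and the difference between treatments was not tested.

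With the marker score as a covariate, 8 of 21 cholesterol biosynthesis genes were called lower in KO against wild type with fibrils, such as Hmgcs1 (-1.29 ± 0.23, adjusted p = 0.00609), and the list had a median of -1.50. The score did not overlap between the groups (0.89 to 2.55 in KO, -0.98 to -0.71 in wild type). These differences are thus extrapolated along the score and were not seen directly. The measured list mean was 6.18, 6.11, 5.54, 3.99 and 4.85 log2 CPM in KO against 5.60 to 5.84 in wild type. Genes of the list vary together (estimated correlation 0.877 without the covariate, against the preset 0.01), so the test of the list at the preset value is no measure here, and an estimated correlation was not run in this model. It had a median of -0.14 without the covariate and was not called there (camera adjusted p = 0.0869). Hmgcs1 was chosen after its values were seen, and 69 genes were called in that model.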
